A study of Mus musculus with 4 samples.

How the data were processed

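The series holds 4 arrays with paired dye channels that compared RNA from the dentate gyrus of the hippocampus of young male C57BL/6J mice. On every array, the Cyanine-3 (green) channel held RNA of mice given only MK-801, a blocker of NMDA-type glutamate receptors, and the Cyanine-5 (red) channel held RNA of mice given MK-801 and then trained in contextual fear conditioning. The arrays stand for 1, 2, 4 and 6 h after the last shock, with 1 array per time and separate drug-only mice at each time. The number of animals behind each RNA and any pooling are not given in the sources used here. All arrays have the same dye orientation, so a gene-specific dye effect cannot be separated from the mean over times, although one that is equal on all arrays drops out of a time trend.

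The deposited table holds 1 signed log ratio per feature and array, read here as log10; the base, the direction, the normalization, the scanner and the software are not given in the sources used here. The reading as log10 rests on the number format alone and is not a stated fact. The design written before the data were examined assumed log2 ratios. Since the base is open, values are given in deposited units without conversion, and a fold is given only with the base it assumes; the limma tests do not depend on the base. The ratio likely runs Cyanine-5 over Cyanine-3, conditioned over drug only, which rests on the dyes named in the labels and on the usual form of such ratios. The sample titles name the drug-only RNA first, an order that could be read as the opposite ratio. The median of every column as deposited was 0, which many exact zeros help to give, so whether the values had been centred is unknown. No intensity or background is in the table, so which features lay above background is unknown; the number of arrays limits the precision.

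Of 16281 features, 13738 had exactly 1 gene symbol in the platform annotation, 52 had several and 2491 had none. For 13694 the symbol was checked through the gene number, which changed 0 symbols, and 44 kept the annotation's own symbol. The named features covered 10698 symbols. No genome build is named, so no coordinates are given. There were 0 blank cells, but 469 features stood at exactly 0 on all 4 arrays and were left out. Another 3897 stood at exactly 0 on 1 to 3 arrays and kept that value before centring. Each array was centred on its median and features of 1 gene were averaged, which left 12779 genes and unnamed features, 10683 of them named genes. Centring changed only the 2 h array, where an exact 0 became 0.000293 and so counts as positive.

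Analyses used R 4.3.3 with limma 3.58.1, and Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib. The mean over times was tested against 0 with lmFit and eBayes (intercept only), and the time trend as the slope on hours after the last shock, both with Benjamini-Hochberg adjustment and a threshold of 0.05, both tests two-sided. P-values measure the spread between arrays of different times, which holds time, animals and technical error together. With 1 array per time, no p-value was computed for a single time; genes were counted beyond 0.176 units, which is 1.5-fold if the base is 10. Pearson's r was computed over genes for the 6 pairs of arrays. For 28 gene lists written down before the data were examined, limma camera was run with a preset inter-gene correlation of 0.01 and with an estimated one, and each list's median on each array was ranked among medians of 10000 random lists of the same size. Random lists were drawn from all genes and unnamed features together, whereas the 28 lists hold named genes only. Lists were not matched on expression, which a ratio table does not hold. An exact sign-flip test over the list medians of the 4 arrays cannot give a two-sided p below 0.125.

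The named genes followed a rule fixed before the data were examined, over genes with exactly 1 symbol. For the mean over times it takes the 10 largest in each direction past the threshold with the same sign on all arrays, or, where fewer than 5 pass, the 5 of that direction with the smallest p. For each time it takes the 4 highest and 4 lowest genes. For the trend it takes the 5 steepest each way past the threshold or, where none passes, the 3 with the smallest p each way. It adds up to 4 members of each list described, those with the largest absolute mean, and a set of genes named wherever measured, of which Nfkb1 and Grin1 were not measured here. Other genes are said to have been chosen after their values were seen.

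The tests were checked on simulated data over 12779 genes with 200 changed ones, made by shuffling the values across genes within each array. The mean over times recovered 0% of genes shifted by 0.3, 57.5% of those shifted by 0.6 and 93.5% of those shifted by 1, with 0 false calls at each size. The time trend recovered 0% at 0.2 units per hour and 72% at 0.4, with 1 false call. In 100 simulated lists of 20 genes without a shift, camera called 6 for the mean and 3 for the trend. Shuffling removes correlation between genes, so this does not check the preset correlation for lists whose genes vary together. It also removes what the arrays share, so false calls from a dye or feature effect shared by the arrays were not checked. For the mean, the full shift was added to every array, also to the 2 h array, whose SD was only 0.0565. Recovery of real changes, if these are smaller on that array, may therefore be lower.

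Alternatives fixed beforehand were values without centring, arrays scaled to equal spread, quantile normalization, each feature on its own, a value on at least 3 arrays, features with an exact 0 left out, robust eBayes, array weights, a size floor, an adjusted p under 0.1, other fold thresholds, other time scales, Spearman's rho, a rank-based and an estimated-correlation camera, and leaving out each array. Alternatives chosen after seeing the data were exact 0 taken as missing, base 2 for the fold counts, exact 0 left out for the lists, exact 0 left out for the genes named at 1 time, and removal of the median of the surrounding 13 by 13 places of a feature grid inferred from feature numbers. Wherever the local median was removed, features with an exact 0 on any array were left out too, so that alternative changes both choices together.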

Results

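Gene expression in the dentate gyrus was compared between mice given MK-801 alone and mice given MK-801 and then conditioned. MK-801 blocks NMDA-type glutamate receptors. The labels state a dose of 300 µg per g body weight, far above the doses usual in mice, so its unit is in doubt. It was given 1 h before conditioning, in which mice spent 2 min in an unfamiliar chamber before each of 3 foot shocks of 1 s at 0.5 mA. RNA was taken at 1, 2, 4 or 6 h after the last shock, with 1 array per time and no replicate at any time. Values are log ratios in deposited units, whose base is not stated. A positive value likely means more RNA in conditioned mice, from the dyes in the labels. The direction is not stated either, and the sample titles name the drug-only RNA first.

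The arrays differed several-fold in spread. Leaving out exact zeros, the SD over features was 0.403 at 1 h, 0.0565 at 2 h, 0.26 at 4 h and 0.242 at 6 h, and the deposited median was 0 on each. Exact zeros made up 21.4% of features at 1 h, 3.72% at 2 h, 8.48% at 4 h and 7.01% at 6 h. Over genes with several features, the SD between features of 1 gene was 0.417 at 1 h, 0.0515 at 2 h, 0.238 at 4 h and 0.317 at 6 h. Over all named features, a wider set, it was 0.403, 0.0574, 0.258 and 0.248. The SD within genes was thus larger at 1 and 6 h and slightly smaller at 2 and 4 h. Paired features of 1 gene had a Pearson's r of -0.0569, 0.113, 0.0527 and 0.00394 at 1, 2, 4 and 6 h. Their Spearman's rho was -0.0619, -0.00457, 0.0972 and 0.108, so features of 1 gene went together little.

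**Figure D1:**
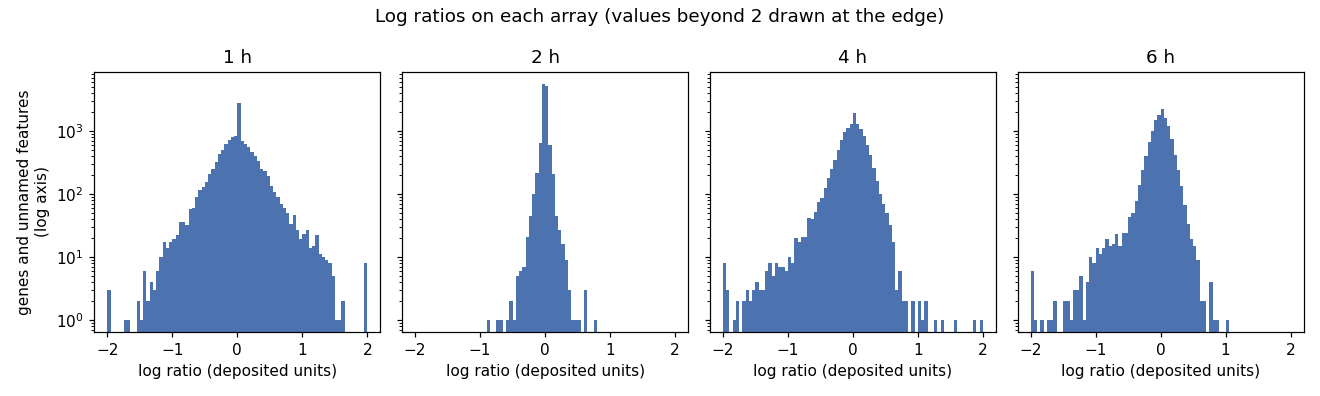
Histograms of centred log ratios (x axis, deposited units; values beyond 2 either way are drawn at the edge) for the 12779 genes and unnamed features (y axis, number, log axis), 1 panel per time. The 2 h array is the narrowest, and the 4 h and 6 h arrays have long negative tails.

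The first comparison asked what differed at each time. At 4 h the highest named genes were Cenpa (2.42), a centromere protein, Sox11 (1.86), a transcription factor of immature neurons, Arc (1.59), an immediate early gene of synaptic plasticity, and Inhba (1.38), which encodes an activin subunit and is induced by neuronal activity. Arc stood at 0.344, 0.0337 and -0.0244 at 1, 2 and 6 h, and Inhba at -0.0787, 0.0708 and 0.0202. Other genes of neuronal activity at 4 h were Gadd45b at 1.08, Dusp6 at 0.651, Nptx2 at 0.507, Bdnf at 0.378, Junb at 0.276 and Ppp1r15a at 0.254, whereas Egr1 stood at 0.0962, Nr4a1 at 0.154, Pim1 at 0.0497, Fosl1 at -0.152 and Fos at -0.271. Dusp6 was about as high at 1 h (0.568), with -0.151 and -0.221 at 2 and 6 h, while Pim1 stood at 0.516 (features at -0.112 and 1.14) and Ppp1r15a at -1.08 at 1 h. The lowest at 4 h were Vamp1 (-2.93), a synaptic vesicle protein, Igfbpl1 (-2.75), Fbln2 (-2.64) and Racgap1 (-2.22).

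Features of the activity-related genes did not always go together at 4 h. Both features of Gadd45b were high (0.941 and 1.21), as were those of Bdnf (0.236 and 0.521). Homer1 had features at 0.247, -0.0831, 0.94 and -0.0194, and Fos had features at 0.0462 and -0.588. The low Fos feature (number 15860) lay near features of Fbln2 (15857, -2.64) and Hspa1b (15862, -0.65), which were low at 4 h too. The averaged value of Fos may thus carry an effect of place on the array, which was not tested. Cenpa, Sox11, Arc and Inhba each rested on 1 feature.

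**Figure D2:**
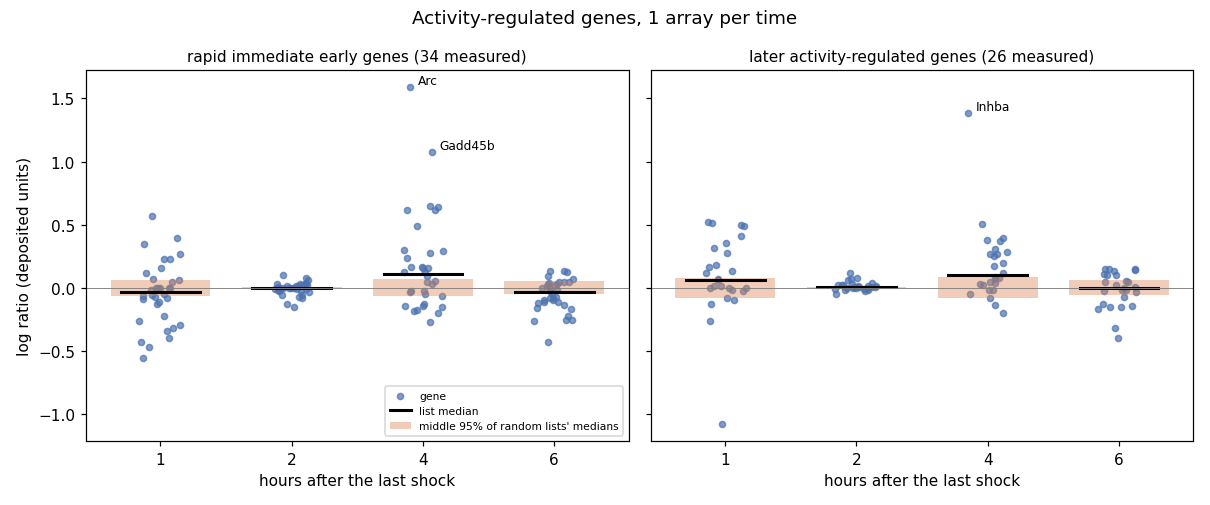
Log ratios (y axis, deposited units) of rapid immediate early genes (left) and later activity-regulated genes (right) by hours after the last shock (x axis), 1 array per time. Points are genes, black bars list medians, and shaded bands the middle 95% of medians of random lists; at 4 h the medians, 0.11 and 0.099, lie above their bands.

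At 1 h the highest genes were Scin (3.04), an actin-severing protein, Gfra3 (2.46), a receptor for a neurotrophic factor, Ttc9c (2.45) and Scml2 (2.32), and the lowest were Sdc3 (-2.77), Map3k7 (-2.05), Rab36 (-1.95) and Ppia (-1.72). At 2 h they were 3110082I17Rik (0.774), Mrps24 (0.649), Patz1 (0.635) and Sim1 (0.628) at the top, and Unk (-0.877), Sp1 (-0.703), Eola1 (-0.699) and Gnpda2 (-0.578) at the bottom, of which Gnpda2 and Eola1 lay 3 feature numbers apart. Sp1 (feature number 17322) lay near Neurod6 (17324), which stood at -0.315 at 2 h. At 1 and 4 h Sp1 stood at 0.128 and 0.129, and Neurod6 at -0.378 and -0.156. At 6 h the highest were Klhdc8b (1.02), 4933402E13Rik (0.892), Klhl14 (0.797) and Gtf3c2 (0.794). The lowest at 6 h were Sdc3 (-2.36), Hes1 (-2.2), Lhx1 (-2.12) and Nfkbib (-1.97). These 4 lay within 8 successive feature numbers, of which 7 were below -0.9 at 6 h and 7 at exactly 0 at 4 h. At 1 h they were low too, with -2.77 for Sdc3, -0.996 for Hes1, -1.41 for Lhx1 and -0.953 for Nfkbib.

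Beyond 0.176 units, 1.5-fold if the base is 10, lay 2933 genes and unnamed features on the positive side and 2815 on the negative side at 1 h, 76 and 131 at 2 h, 2092 and 2193 at 4 h, and 1268 and 1465 at 6 h. At 1.5-fold with base 2, they numbered 573 and 474 at 1 h, 4 and 3 at 2 h, 54 and 277 at 4 h, and 11 and 183 at 6 h. The positive share of those past 0.176 was 51.0%, 36.7%, 48.8% and 46.4% at 1, 2, 4 and 6 h, but 48.0%, 47.3%, 51.6% and 51.5% after quantile normalization, so the larger side turned at 1, 4 and 6 h. Quantile normalization gives the features of every array the same distribution, so the shares after it do not measure the balance of each array. With 1 array per time these sizes carry no test.

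The second comparison asked which genes differed the same way at all times. The strongest was Mrps24, a mitochondrial ribosomal protein gene, with a mean of 0.598 ± 0.0437 (SE, n = 4 arrays), and 0.575, 0.649, 0.593 and 0.576 at 1, 2, 4 and 6 h. The next were 3110082I17Rik (0.584 ± 0.0761), Slc25a3 (0.236 ± 0.0488), a mitochondrial phosphate carrier, Rps26 (0.252 ± 0.0537) and Ube2n (0.268 ± 0.0573), each positive at all 4 times. On the negative side stood H2ax (-0.365 ± 0.0589), a histone variant marked at DNA breaks, Neurod6 (-0.303 ± 0.0566), a transcription factor of excitatory neurons, Zfyve19 (-0.287 ± 0.0537), Mrpl52 (-0.268 ± 0.0501) and Timm13 (-0.292 ± 0.0557), each negative at all 4 times. With arrays scaled to equal spread the means were 0.959 for Mrps24, 1.07 for 3110082I17Rik, 0.37 for Slc25a3 and -0.475 for Neurod6, and after quantile normalization -0.561 for H2ax, -0.504 for Neurod6, -0.443 for Zfyve19, -0.426 for Mrpl52 and -0.458 for Timm13; Rps26 stood at 0.168 with array weights. None passed: the limma adjusted p was 0.328 for Mrps24 and 0.725 for the other 9.

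Of 12779 genes and unnamed features, limma called 0 at an adjusted p under 0.05, and 570 had an unadjusted p under 0.05 against 639 expected by chance. With array weights, which gave the 2 h array 6.86 and the 1 h array 0.265, 2 passed, Mrps24 (limma adjusted p = 0.00811, against 0.328 to 0.794 under the other alternatives) and 3110082I17Rik (limma adjusted p = 0.0301, against 0.544 to 0.794). A dye effect of a gene would add to these means.

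The third comparison asked which genes moved steadily with time. The 3 falling genes with the smallest p were Nxf1, an mRNA export receptor, with a slope of -0.313 ± 0.027 per hour (SE, n = 4 arrays), Ccnt1, a subunit of an elongation factor, with -0.268 ± 0.0266, and Med22, a subunit of Mediator, with -0.294 ± 0.0335. On the rising side were Tex47 (0.202 ± 0.0424), Tmed10 (0.125 ± 0.0263) and Magi3 (0.165 ± 0.0365). None passed, with a limma adjusted p of 0.741 for each; limma called 0 genes, and 451 had an unadjusted p under 0.05. Each of the falling genes averaged 2 features, which stood at 6 h at -1.92 and -0.63 for Nxf1, -2.02 and -0.0834 for Ccnt1, and -0.519 and -1.88 for Med22. The slope of Ccnt1 was -0.141 with exact zeros left out, -0.165 after quantile normalization and -0.0872 with exact zeros left out and the local median removed, an alternative chosen after seeing the data; that of Med22 was -0.181 after quantile normalization, and those of Tex47 and Magi3 were 0.128 and 0.11 with arrays scaled to equal spread. The second feature of Nxf1 lay 2 feature numbers from that of Sdc3.

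Among the gene lists, cytosolic ribosomal proteins were the clearest. Their list median was 0.0857 at 1 h, 0.073 at 4 h and 0.101 at 6 h, at percentiles 99.9, 99.6 and 100 of random lists. At 2 h it was 0.000293, the value that an exact 0 takes there after centring. Of 67 measured genes, 44 were positive and 12 negative at 1 h, 45 and 20 at 4 h, and 48 and 12 at 6 h. Rpl38 had a mean of 0.259 ± 0.0557, Rpl26 of 0.286 ± 0.0925 and Rps21 of 0.286 ± 0.16, while Rps20 stood at -0.554 ± 0.279 (SE, n = 4 arrays). The list passed limma camera over the 28 lists (adjusted p = 1.04e-05), but not with an estimated correlation (adjusted p = 0.796), and under its other alternatives the adjusted p ran from 9.84e-07 to 0.0328. The exact sign-flip p over the 4 arrays was 0.125, the smallest it can give, and no member passed singly, either over all genes or adjusted over the list alone. A dye effect shared by the arrays would add to this shift, as to that of any list over all times, and was not measured. Random lists were not matched on expression.

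Genes of oxidative phosphorylation had list medians of 0.000906, 0.000293, 0.0532 and 0.0484 at 1, 2, 4 and 6 h (percentiles 93.3, 68.4, 97.9 and 99.3). The 2 h median is again the value of an exact 0 after centring. At 4 h the percentile was 93.75 with each feature on its own, 96 with exact zeros left out and 97.2 with the local median removed as well. Uqcr11 had a mean of 0.196, Ndufc1 of 0.184 and Atp5g1 of 0.206, while Atp5j stood at -0.246; the values of Atp5g1 and Atp5j hold exact zeros. The list missed the threshold (camera adjusted p = 0.0901, and 0.796 with an estimated correlation). It passed with exact zeros left out and the local median removed (camera adjusted p = 0.0253), an alternative chosen after seeing the data.

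Rapid immediate early genes had a median of 0.11 at 4 h, at percentile 99.9, with 21 of 34 genes positive and 13 negative. At 1, 2 and 6 h their percentiles were 7.17, 44.9 and 6.62. Later activity-regulated genes, such as Inhba, Nptx2 and Bdnf, had a median of 0.099 at 4 h, at percentile 99.03, with 20 of 26 positive, or 95.9 with exact zeros left out. The later list was not high at 4 h alone. It had medians of 0.0627, 0.00571 and 0.0017 at 1, 2 and 6 h, at percentiles 95.87, 90.67 and 51. Over all times the rapid list gave a camera adjusted p of 0.952 and the later list one of 0.0524 (0.796 with an estimated correlation); the later list passed in a rank-based camera (adjusted p = 0.0332) and without the 6 h array (adjusted p = 0.00491).

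Several lists of cell type markers stood high on 1 or 2 arrays. Dentate granule cell markers had a median of 0.0262 at 2 h (percentile 99.34) and of 0.249 at 6 h (percentile 100), with 7 of 8 genes positive at each, against percentiles 68.3 and 24.4 at 1 and 4 h; Prox1 stood at 0.286, Sema5a at 0.278, Pitpnm2 at 0.241, Tdo2 at 0.208 and Trpc6 at 0.373 (features at 0.156 and 0.59) at 6 h. Oligodendrocyte and myelin markers had a median of 0.12 at 6 h (percentile 100), with 18 positive and 4 negative; Mbp, a myelin protein gene, stood at 0.132 and Gjb1 at 0.0627, but Olig1 at -0.0442, Pdgfra at -0.103 and Sox10 at -0.178. Genes of GABA synthesis, transport and receptors had a median of 0.29 at 1 h (percentile 99.9), with 9 genes positive and 4 negative, but 0.00635 when features were not averaged by gene. Gabbr1 stood at 0.983, Gabra5 at 0.903 and Gabra6 at 0.693 (features at exactly 0 and 1.39), but Gabrd at -0.612. Neurogenesis and cycling markers had a median of 0.113 at 1 h (percentile 98.8, but 96.45 with exact zeros left out), with 16 positive and 7 negative; Cd24a stood at 0.765 and Sox11 at 0.113, but Rrm2 at -1.23, and Igfbpl1 was at exactly 0. Camera called none of these lists over all times (adjusted p = 0.499 for the granule cell and GABA lists, 0.952 for oligodendrocytes and 0.158 for neurogenesis), nor for a time trend (adjusted p = 0.597 for the granule cell, GABA and oligodendrocyte lists and 0.942 for neurogenesis). The neurogenesis list passed over all times with exact zeros left out and the local median removed (camera adjusted p = 0.0196), chosen after seeing the data.

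At 2 h, genes of the heat shock and unfolded protein response had a median of 0.0213 (percentile 100), with Hspa5, an endoplasmic reticulum chaperone gene, at 0.348, Pdia4 at 0.0213 (features from -0.0385 to 0.0999), Hspa1b at 0.0193 and Hsp90b1 at 0.00424; 21 genes were positive and 6 negative. Over all times the list gave a camera adjusted p of 0.623. In all, 16 of the 112 list medians lay outside the middle 95% of random lists, against 5.6 expected by chance. That expectation takes the genes of a list as independent. Genes of a list can vary together, and some lists share genes, so these numbers are no test of an excess.

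**Figure D3:**
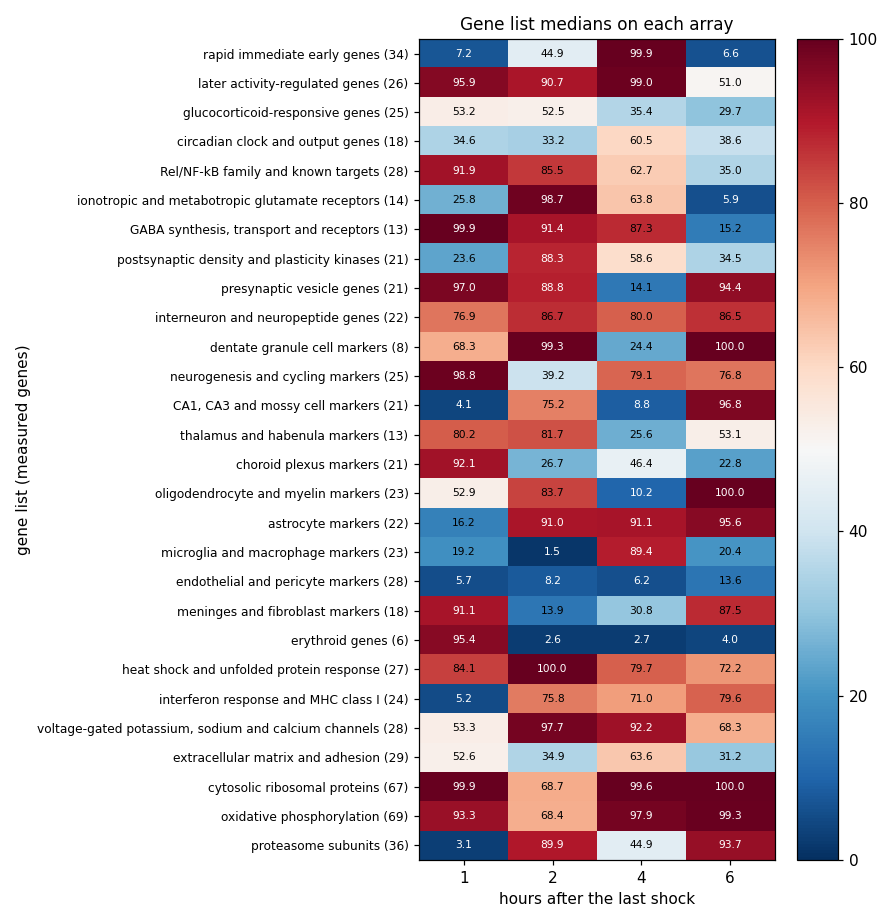
Percentile of each list median (colour and number) among medians of 10000 random lists of the same size, for 28 gene lists (y axis, measured genes in brackets) by hours after the last shock (x axis). Ribosomal proteins lie at 99.6 or above at 1, 4 and 6 h, and rapid immediate early genes stand high at 4 h with 99.9.

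No gene list passed the test for a time trend. The lowest camera adjusted p was 0.163, for erythroid genes, with list medians of 0.194, -0.0267, -0.166 and -0.11 at 1, 2, 4 and 6 h (adjusted p = 0.944 with an estimated correlation). Hbb-b2, a haemoglobin gene, stood at 0.425, -0.195, -0.201 and -0.178, Car1 at 0.147, -0.354, -2.15 and -1.41, Slc4a1 at 0.0936, -0.0282, -0.136 and -0.888 (features at -1.86 and 0.0807 at 6 h), and Epb42 at 1.2, 0.0107, 0.325 and 0.0955. Without the 1 h array, camera called 1 list for a trend, the ribosomal proteins (adjusted p = 1.3e-05). With all arrays that list had a camera adjusted p of 0.597 for the trend (0.944 with an estimated correlation), and its direction turned to falling without the 2 h array (adjusted p = 0.975) and without the 6 h array (adjusted p = 0.966). Adjusted over the list alone, the slope passed for 1 gene each of the endothelial, heat shock and thalamus lists, against 0 over all genes. These were Ramp2, Pdia4 and Tnnt1, each with a feature below -1.2 at 6 h (-1.63, -2.19 and -1.42). The other features stood at -0.151 and -0.0777 for Pdia4 and at -0.144 for Tnnt1.

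The arrays shared little of their pattern over genes. Across 12779 genes and unnamed features, which are not independent replicates, Pearson's r was 0.308 for 2 h with 6 h, 0.177 for 4 h with 6 h, 0.143 for 2 h with 4 h, 0.117 for 1 h with 4 h, 0.0643 for 1 h with 2 h and -0.0187 for 1 h with 6 h, with a mean of 0.132. In the same order, Spearman's rho was 0.368, 0.153, 0.182, 0.14, 0.105 and -0.0414. After centring, 10192 genes were at 0 on no array, with exact zeros at 2 h counted as positive. Of these, 2187 had the same sign at all 4 times, 21.5% against 12.5% for independent signs. A dye effect shared by the arrays would add to both and was not measured.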

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

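The tests in this part were chosen after the result was seen. Ttr, the transthyretin gene, which is very abundant in the choroid plexus, lay in the outermost 1% of genes on opposite sides at different times. Its log ratio was 1.96 at 1 h and -1.19 at 4 h, with -0.16 at 2 h and -0.535 at 6 h, from 1 feature and 1 array per time; the difference between 1 h and 4 h was not tested. After removal of the local median of the array, Ttr stood at 1.96 at 1 h and -1.16 at 4 h. Of genes at 0 on no array, 0.0694% and 0.466% lay as far from 0. This shows only that the median of the surrounding 13 by 13 places was small. The median absolute deviation was 0.318 at 1 h and 0.197 at 4 h, so values as far out as those of Ttr could hardly leave the outermost 1%. Runs shorter than the window are not removed, so an effect of place on the array stays open. Choroid plexus tissue in unequal amounts may account for the values of Ttr. The 20 other choroid plexus markers, however, had a median of 0.0395 at 1 h (percentile 88.7) and 0.0114 at 4 h (percentile 60.6), inside the middle 95% of random lists. Unequal tissue stays open, since the table does not show whether those markers lay above background. An effect of conditioning at these times was not tested.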

How the results depend on the processing

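No gene passed the adjusted p for the mean over times or the time trend under any alternative run, except with array weights, where 2 passed for the mean; the cause was not tested. Elsewhere the smallest limma adjusted p ran from 0.328 to 0.794 for the mean and from 0.288 to 1 for the trend. Requiring a value on at least 3 arrays removed nothing, as no cell was blank. Genes past 1.5-fold numbered 5748, 207, 4285 and 2733 at 1, 2, 4 and 6 h with base 10. With arrays scaled to equal spread they numbered 2606, 2443, 1833 and 1807, at 2-fold 3389, 44, 1712 and 815, and with base 2, chosen after seeing the data, 1047, 7, 331 and 194; at 1.3-fold they numbered 575, 6590 and 5022 at 2, 4 and 6 h. These counts follow from the thresholds and scales themselves. The mean correlation between arrays of 0.132 was 0.151 with Spearman's rho and 0.11 without the 1% of genes with the largest mean; the cause was not tested.

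Of the gene lists, 1 shifted over all times. With an estimated correlation 0 did, with a rank-based camera 2, and with exact zeros left out and the local median removed, chosen after seeing the data, 3, adding oxidative phosphorylation (adjusted p = 0.0253) and neurogenesis markers (adjusted p = 0.0196); leaving out each array gave 1 to 2. For time trends, 0 passed, and leaving out each array gave 0 to 1. The cause was not tested. No called result reversed, but 7 values of single genes changed sign with exact zeros left out and the local median removed: Mbp (-0.0218 to 0.141), Junb, Fkbp5 and Sgk1 at 1 h, Homer1 at 2 h, and Arc and Grin2b (0.148 to -0.00577) at 6 h. With exact zeros left out alone, Homer1 changed sign and Grin2b stood at 0.0242. The larger side of the 1.5-fold counts turned at 1, 4 and 6 h after quantile normalization, which gives all arrays 1 distribution and so cannot show the balance of each. The 131 values named for single genes, lists and pairs were each set against their alternatives: in 630 of these comparisons the value kept its side or moved within its spread, in 67 it moved further and in 2 it became stronger. No paired analysis was possible because each time is 1 array. Signal over background is not in the table, so its limit is unknown.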

Other observations

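Glucocorticoid-responsive and circadian clock genes, lists fixed beforehand for this treatment, stayed inside the middle 95% of random lists. Glucocorticoid-responsive genes had medians of 0, -0.000751, -0.000718 and -0.00975 at 1, 2, 4 and 6 h, and at 4 h 12 were positive and 13 negative, 7 and 2 of them past 0.176. Mt2 stood at 0.355 and Cdkn1a at 0.159 at 4 h, but Zbtb16 at -0.000718, Sgk1 at -0.104, Ddit4 at -0.106 and Fkbp5 at -0.383; Ddit4 was negative at all 4 times. Circadian clock genes had percentiles between 33.2 and 60.5, with Timeless at 0.272, Npas2 at -0.531 and Dbp at -0.815 at 4 h and Rora at exactly 0. The Rel/NF-kB list had percentiles of 91.9, 85.5, 62.7 and 35.0, with Traf1 at 0.139 (features at 0.277 and exactly 0), Rela at -0.0823, Nfkbib at -0.953 and Cxcl1 at exactly 0 at 1 h. Rel stood at -0.307 at 1 h and 0.236 at 4 h, but its features went apart: they were at exactly 0 and -0.614 at 1 h, and at 0.463 and 0.00912 at 4 h, so that with exact zeros left out Rel stood at -0.602 and 0.0148. Glutamate receptor genes had a median of 0.0156 at 2 h (percentile 98.7, but 75.05 with exact zeros left out) and -0.0619 at 6 h (percentile 5.87); Grin2c stood at -0.571 and Grik2 at -1.12 at 1 h, Grin2a at -0.267 (-0.522 with exact zeros left out), and at 4 h Grin2b stood at 0.269 and Gria1 at 0.433. Endothelial and pericyte markers had negative list medians at each time, inside the middle 95% of random lists, with percentiles of 5.71, 8.19, 6.17 and 13.6 and a camera adjusted p of 0.499; Eng stood at -0.0715, -0.143, -0.298 and -0.412 and Kdr at -0.364, -0.0635, -0.676 and -0.142, while Ramp2 and Itm2a were positive at 1 h (0.384 and 0.0556) and stood at -1.63 and -0.865 at 6 h; the features of Itm2a were at 0.111 and exactly 0 at 1 h, and at -0.186 and -1.54 at 6 h. Microglia and macrophage markers lay at percentile 1.5 at 2 h, with C1qa at -0.104, Cd14 at -0.0202, Laptm5 at -0.0148 and Cd68 at 0.0128, but at 25.35 with each feature on its own and at 22.4 with exact zeros left out and the local median removed. Astrocyte markers lay at percentile 95.6 at 6 h, inside the middle 95% of random lists, with 14 genes positive and 7 negative. Gfap stood at 0.153, Glul at 0.173, Mt3 at 0.18, Slc4a4 at 0.19 and Aldh1l1 at 0.129.

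The spread (median absolute deviation) of the 2 h array, 0.0268, was 0.0891 after multiplication by the factor between base-10 and base-2 logarithms, below the lowest of the other arrays, 0.144.

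All the tests below were chosen after the result was seen. Rapid immediate early genes were positive as a list at 4 h. With exact zeros left out the list kept 29 genes and a median of 0.129 (percentile 99.9). With the local median removed as well, the list median was 0.162 (percentile 100), so the removal did not lower it. Runs shorter than the window are not removed, and the feature grid was inferred from feature numbers. The list may therefore still carry an effect of place on the array. Its medians at 1 and 6 h were -0.0358 and -0.0361, below the 4 h median of 0.11 by 0.146 each, more than the half-widths of random lists at both times added (0.131 and 0.118), which argues against a dye effect of like size on these arrays; the narrow 2 h array was not used for this. Noise of single features stays open: the 9 genes with several features not at 0 had an intraclass correlation of 0.469 between features (permutation p = 0.0799), and in 4 of them all features were positive. An effect of conditioning at 4 h may be behind the list, but 1 array leaves it untested.

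The lowest 1% of features at 6 h, 151 features below -1.2, were often neighbours by feature number: 25.2% had a neighbour among them, against at most 7.95% in 1000 random draws, which is consistent with an effect of place on the array. The highest 1% at 6 h had 2.65%; the lowest 1% had 12.8% at 2 h, also above every draw (at most 7.69%), and 7.81% and 9.4% at 1 and 4 h, equal to the highest draw. An effect of the feature shared by the arrays stays open: over those not at 0, these features had a median of -0.368 at 4 h and -0.0336 at 2 h, below all 1000 random draws, but 0.183 at 1 h, above all of them, and 10 (7.69%) were in the lowest 1% at 4 h, with 1.26 expected by chance. Sdc3, Hes1, Lhx1 and Nfkbib lie in such a run, where 4 of the 5 features not at 0 at 1 h were below -0.9 there too. Their values may therefore come from their place on the array or from such a shared effect. Features of Nxf1, Ccnt1 and Med22 (-1.92, -2.02 and -1.88 at 6 h) were in this lowest 1% too. So were features of Ramp2, Pdia4 and Tnnt1 (-1.63, -2.19 and -1.42). Among others, features of Car1 and Slc4a1 of the erythroid list (-1.41 and -1.86), Itm2a (-1.54) and Atp5j (-1.69) belonged to it as well. The falling slopes of these genes may carry the same effects.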
